A study of Arabidopsis thaliana with 24 samples.

How the data were processed

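Roots of Arabidopsis thaliana were collected 6 days after seedlings were moved into light and grown upright at 22 °C under long days, with about 20 plates per sample. The plants carried a ribosomal protein L18 with a His and FLAG tag (HF-RPL18), so that ribosomes and the mRNAs on them could be pulled down with an anti-FLAG M2 resin. The tagged protein was driven either by the viral 35S promoter or by a promoter named for a root layer: ACR4 (columella), SHR (stele), SCR (endodermis), CO2 (cortex) or WER (epidermis). Each of the 6 lines was made in the Col0 wild type and in the hyl1 mutant, and each of the 12 groups had 2 libraries, 24 in all. The libraries were sequenced on an Illumina MiSeq. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The library numbers run from 223 to 238 for the 35S, ACR4, SCR and CO2 lines, from 320 to 323 for the SHR line and from 89 to 92 for the WER line. A comparison of genotypes stayed within 1 run of numbers, while the SHR and WER lines cannot be separated from their batch in comparisons between lines.

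The deposited values were raw read counts per gene for 33602 genes in 1 table, made with featureCounts from the Subread package, per the submitters' processing notes. The same notes name CASAVA 1.8.2, TopHat2 2.0.11, Bowtie2 2.2.1.0 and the TAIR10 genome. The featureCounts version, the use of strand and the treatment of reads with several matches are not given in the sources used here, so near-identical copies, overlapping genes and antisense partners may share reads. Totals ran from 2868803 to 13575556 counts per library. Gene symbols were taken from a table of the TAIR10.1 assembly, which held 32835 of the 33602 identifiers (97.7%). Since the builds differ, only names and the order of genes along the chromosomes were taken from it. Protein sequences for the motif test in the closing section were translated from that assembly.

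Counts were tested as deposited with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood F test on a design of 12 groups with TMM scaling. Genes were kept with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 23219 genes. All 24 libraries shared 1 estimate of the spread, with a common dispersion of 0.126. Adjusted p is the Benjamini-Hochberg value over all tested genes, and genes with an adjusted p under 0.05 were called. The comparisons were hyl1 minus Col0 as the mean of the 6 lines and in each line, the difference of that effect between lines, and each Col0 layer line minus the mean of the 4 other layer lines. Normalised CPM were computed on the TMM-scaled library size, with SD over 2 libraries. Scaling left the median log2 fold change of all genes within 0.1 of 0 except in the WER line, where it was −0.24. A fold against a group with 0 counts in both libraries is given as a lower bound against 3 counts over that group, and such bounds cover counting error only. Genes with 1 to 3 counts in a group are given as CPM.

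Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 on log2 CPM. The same test was run with an estimated correlation, and fry was run as a test of whether members moved 1 way on balance. The adjusted p of the miRNA target list is over the 7 hyl1 comparisons, and that of a layer's own marker list over the 5 layer comparisons. The adjusted p of other lists is over the 16 lists in all comparisons of that kind. The 16 lists were miRNA targets, TAS loci, small RNA machinery, shoot photosynthesis, cell division, heat shock, jasmonate and touch, auxin response, abscisic acid response, flavonoid and anthocyanin, pri-miRNA, and markers of columella and root cap, stele, endodermis, cortex, and epidermis with root hair. The miRNA target list held 115 genes of 30 families. The pri-miRNA list held the 178 miRNA genes found in the count table, of which 32 were tested.

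The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names HYL1 and RPL18B first. It then names, from each list, up to 4 called members with the largest change, up to 12 for miRNA targets, or the 2 most expressed where none was called. For the mean hyl1 effect it names the 8 largest rises and the 8 largest falls with the same sign in all 6 lines, and for each line the 3 largest rises and the 3 largest falls. For the difference between lines it names the 5 smallest p, and for each layer the 5 largest enrichments and the gene of the promoter. Genes named for their change had a mean log2 CPM of at least 2. The text names part of the genes this rule gives. The result of 1 of these genes is not reported here.

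The tests were checked on simulated counts drawn from the means and library sizes of these samples, with 100 genes changed 2-fold and 100 changed 4-fold. Each simulated gene had 1 mean over all libraries and 1 spread in all groups. Beyond the changed genes the simulated lines did not differ, and no library diverged. The rates below therefore need not hold where replicates differ more, such as hyl1 in the WER line. For the mean of the 6 lines, 58% of the 2-fold and 88% of the 4-fold genes were called in the right direction, with 9 unchanged genes called among 22594. For hyl1 minus Col0 in the CO2 line these shares were 2% and 33%, with 1 unchanged gene called among 22591. For the Col0 SCR line against the 4 other layer lines they were 13% and 53%, with 4 unchanged genes called among 22581.

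The alternatives were DESeq2 1.42.0 with its own size factors, RLE size factors, no filter on low counts, each library left out in turn, the replicate number as a block, a fit of each line alone, library sizes without organelle genes and RPL18B, only the 4 lines numbered together, and the layer contrasts in the hyl1 libraries. Alternatives chosen after the values were seen were the fits without the WER libraries, of only the 35S, SHR and CO2 lines, and with hyl1 WER replicate 2 left out of the shared spread. Replicates of each group differed by more than sampling noise, with chi-square per degree of freedom from 4.32 to 93.3, so each was counted as 1 sample. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and Biopython 1.88 was used for motif counts, and matplotlib 3.10.9 for the plots. Neighbouring genes were counted in R.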

Results

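RNA from anti-FLAG pull-downs of ribosomes was counted in 24 root libraries of Arabidopsis thaliana, 2 for each of 12 groups made of 6 HF-RPL18 lines in Col0 or hyl1. HYL1 is a double-stranded RNA binding protein that works with DCL1 (AT1G01040) to cut microRNAs from their primary transcripts. The comparisons ask which ribosome-associated transcripts differ in hyl1, whether they differ alike in each line, and which transcripts mark each root layer in Col0. Total counts per library were 4686323 to 9614835 in the 35S line, 6526801 to 8589721 in the ACR4 line, 5738367 to 7027091 in the SCR line and 5416522 to 6464178 in the CO2 line. They were lowest in the SHR line, at 2868803 to 4018367, and highest in the WER line, at 10686837 to 13575556. Between 22330 and 30265 genes had at least 1 count in a library.

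HYL1 (AT1G09700) had 34 to 145 counts in the 12 Col0 libraries (5.34 to 15.4 normalised CPM) and 1 to 43 counts in the 12 hyl1 libraries (0.109 to 9.95 CPM). Its mean log2 fold change over the 6 lines was −1.67 (SE 0.34, edgeR adjusted p = 0.00185), with a lower mean in hyl1 in 6 of 6 lines. Within single lines only the WER line passed the test, at −2.35 (SE 0.83, adjusted p = 0.0328), and it lost this call in 3 of 4 fits with 1 WER library left out (adjusted p = 0.0531, 0.107 and 0.0582 without Col0 WER replicates 1 and 2 and hyl1 WER replicate 1). In fits of the 4 libraries of a line HYL1 passed in the 35S line (adjusted p = 0.0126) and the ACR4 line (0.0174), and without hyl1 WER replicate 2 in the shared spread in the ACR4 line (0.0251) and the SCR line (0.0125). The values were −1.82 in the 35S line, −1.73 in the ACR4 line, −2.51 in the SCR line, −1.03 in the CO2 line and −0.61 in the SHR line. The hyl1 libraries kept the most HYL1 reads in the SHR line (9.21 against 14.03 CPM in Col0) and the CO2 line (5.34 against 10.9 CPM), and the hyl1 allele was not given in the sources used here. RPL18B (AT3G05590), the native gene of the tagged protein, had 15335 to 18635 CPM in the 35S libraries and 1212 to 5572 CPM in the libraries of the 5 layer lines. Reads from the tagged copy may be counted under this gene, so these values do not measure the native gene alone.

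**Figure D1:**
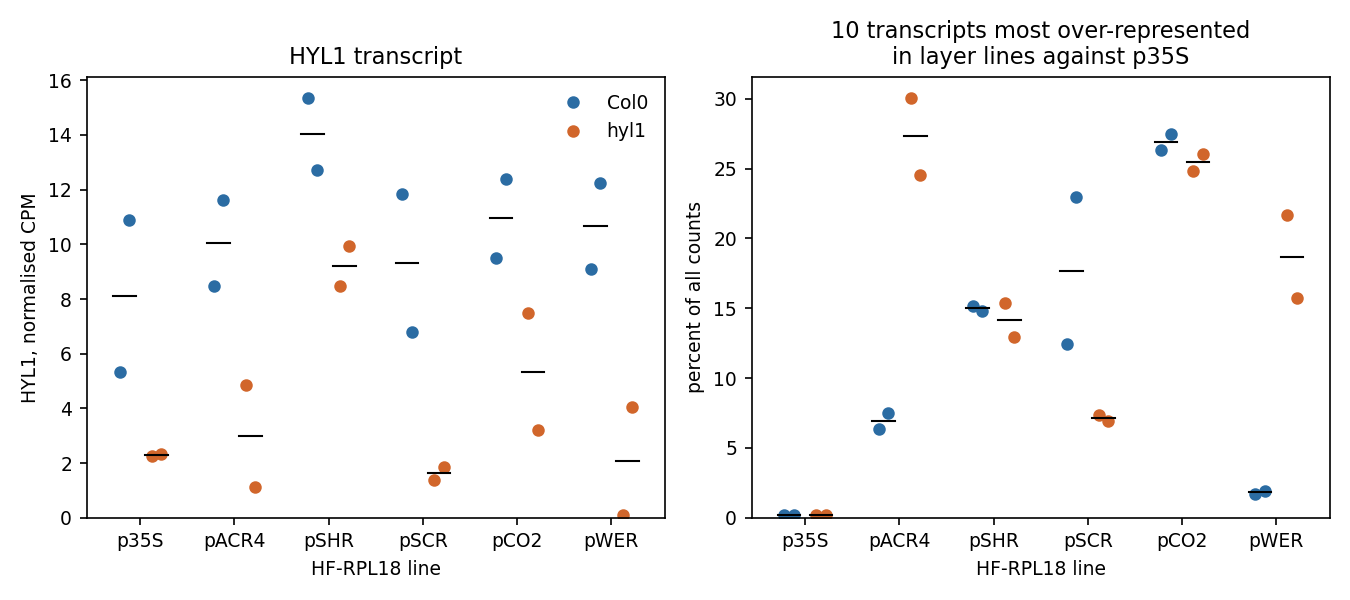
Left, HYL1 in normalised CPM per library, by line and genotype; right, the percent of all counts taken by the 10 transcripts most over-represented in the layer lines against the 35S line. Dots are libraries and bars are means of 2; HYL1 lies between 5.34 and 15.4 CPM in Col0 and between 0.109 and 9.95 CPM in hyl1.

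A few transcripts took a large part of the layer pull-downs. The 10 most over-represented against the 35S line, led by AT5G35200, AT1G64880 and AT1G60095, held 0.221% of the counts in Col0 and 0.208% in hyl1 in the 35S line. In the ACR4 line they held 6.91% in Col0 and 27.3% in hyl1, in the WER line 1.83% and 18.7%, and in the SCR line 17.7% and 7.16%. The shares of the 2 genotypes were closer in the SHR line (15.01% and 14.2%) and the CO2 line (26.9% and 25.4%). Replicates of a group correlated with r of 0.926 to 0.975 across genes, except those of hyl1 in the WER line, with r of 0.752. The sum of the endodermis markers was 4796 CPM in Col0 SCR replicate 1 and 1273 CPM in replicate 2, against 4923 and 4417 CPM in the hyl1 SCR libraries.

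In the mean of the 6 lines, the strongest rises in hyl1 were transcripts nearly absent from Col0 ribosomes. AT1G15540 and AT1G52800, a pair of 2-oxoglutarate-dependent dioxygenase genes, had 0 to 0.619 and 0 to 0.594 CPM in the Col0 libraries and 7.04 to 43.8 and 15.8 to 36.3 CPM in the hyl1 libraries (edgeR adjusted p = 1.31e-10 and 6.4e-11). The cytochrome P450 genes CYP712A2 (AT5G06905) and CYP93D1 (AT5G06900) rose from 0 to 1.1 and 0 to 0.991 CPM to 7.83 to 36 and 1.55 to 14.2 CPM (adjusted p = 2.28e-08 and 2.77e-07). The hydroxysteroid dehydrogenase genes HSD4 (AT5G50590) and HSD7 (AT5G50690) rose from 0 to 1.78 CPM to 5.97 to 26.8 CPM (adjusted p = 2.59e-09 and 3.23e-09). They had equal counts in 22 of 24 libraries and may share reads, so which copy rose is uncertain. AT1G52820, another dioxygenase gene, rose by 5.97 on the log2 scale (SE 0.24, adjusted p = 1.78e-11), and AT2G42247 by 4.37 (SE 0.18, adjusted p = 1.78e-11).

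Among the strongest falls in hyl1 were a defensin-like gene, AT3G59930, at −3.88 (SE 0.26, adjusted p = 1.11e-08), the lectin-family gene AT5G35940 at −3.50 (SE 0.43, adjusted p = 1.92e-05) and the extensin-family gene AT5G06630 at −2.71 (SE 0.22, adjusted p = 1.77e-07). PEN3 (AT5G36150), a triterpene synthase gene, fell by 2.65 (SE 0.33, adjusted p = 2.09e-05) and AT5G19110 by 2.55 (SE 0.39, adjusted p = 1.58e-04). AT5G33355, AT4G39675 and AT1G73580 fell as well (edgeR adjusted p = 1.48e-05, 5.24e-06 and 4.07e-05), with ranges that overlapped between genotypes. They had 1.19 to 23.7, 0.253 to 44.4 and 3.14 to 8.72 CPM in Col0 libraries. In hyl1 libraries they had 0 to 1.5, 0 to 5.85 and 0 to 4.91 CPM. In all, 1821 genes were higher and 2786 lower in hyl1. The count of 4607 was 9487 without hyl1 WER replicate 1, 2738 without the WER libraries and 775 (401 higher, 374 lower) in a fit of only the 35S, SHR and CO2 lines. The 16 genes named above kept their calls with any 1 of the 24 libraries left out.

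Targets of microRNAs rose together in hyl1. Of 104 tested targets, 48 rose and 9 fell, and adjusted over the list alone 55 rose and 11 fell, with a median log2 fold change of 0.47 (camera adjusted p = 2.26e-16, and 4.05e-05 with an estimated correlation). The largest rise was in SULTR2;1 (AT5G10180), a sulfate transporter gene targeted by miR395, from 1.52 to 27 CPM in Col0 libraries to 44 to 112 CPM in hyl1 libraries (adjusted p = 1.31e-10). The GAMYB-like transcription factor genes MYB33 (AT5G06100) and MYB65 (AT3G11440), targets of miR159, rose by 2.9 (SE 0.11, edgeR adjusted p = 1.78e-11) and 2.82 (SE 0.18, adjusted p = 9.16e-09). TCP4 (AT3G15030) and TCP3 (AT1G53230), targets of miR319, rose by 2.36 (SE 0.17) and 2.06 (SE 0.24). NF-YA2 (AT3G05690), NF-YA8 (AT1G17590) and NF-YA3 (AT1G72830), subunits of a CCAAT-binding factor targeted by miR169, rose by 2.29 (SE 0.19), 2.12 (SE 0.16) and 2.01 (SE 0.13). AGL16 (AT3G57230), the MADS-box target of miR824, rose by 1.92 (SE 0.12), AGO2 (AT1G31280), the Argonaute target of miR403, by 1.62 (SE 0.14), and the class III HD-ZIP gene ATHB-15 (AT1G52150) by 1.56 (SE 0.10). Adjusted p for the genes from TCP4 to ATHB-15 ran from 4.48e-09 for AGL16 to 1.03e-05 for TCP3.

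Families differed in how many of their targets passed. All 5 tested targets of miR165/166 rose (median 1.18), as did the 3 tested targets of the miR390 and TAS3 pathway (median 1.34). These medians were highest in the ACR4 and WER lines (2.24 and 2.204 for miR165/166, 2.64 and 2.88 for miR390 and TAS3), where stele markers and the share of the dominant transcripts were higher in hyl1 too. In the 35S, SHR and CO2 lines edgeR called 0 members of either group, with medians of 0.41 to 0.53 and of 0.18 to 0.69. For miR159, 2 of 3 rose (median 2.82), for miR169 4 of 7 (1.55), for miR319 3 of 5, for miR161 with miR400 6 of 11 (0.94), for miR395 3 of 4 (0.86) and for miR156 2 of 8 (0.78). DCL1, the target of miR162, rose by 1.11. In single lines it was called only in ACR4 (1.76) and WER (2.28), with 0.05 in SCR to 1.31 in CO2 among the other lines. AGO1 (AT1G48410), the target of miR168, had a log2 fold change of 0.40 that did not pass. For miR172, 1 target rose and 2 fell (median −0.12), and for miR163 1 of 3 fell (median −1.10).

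**Figure D2:**
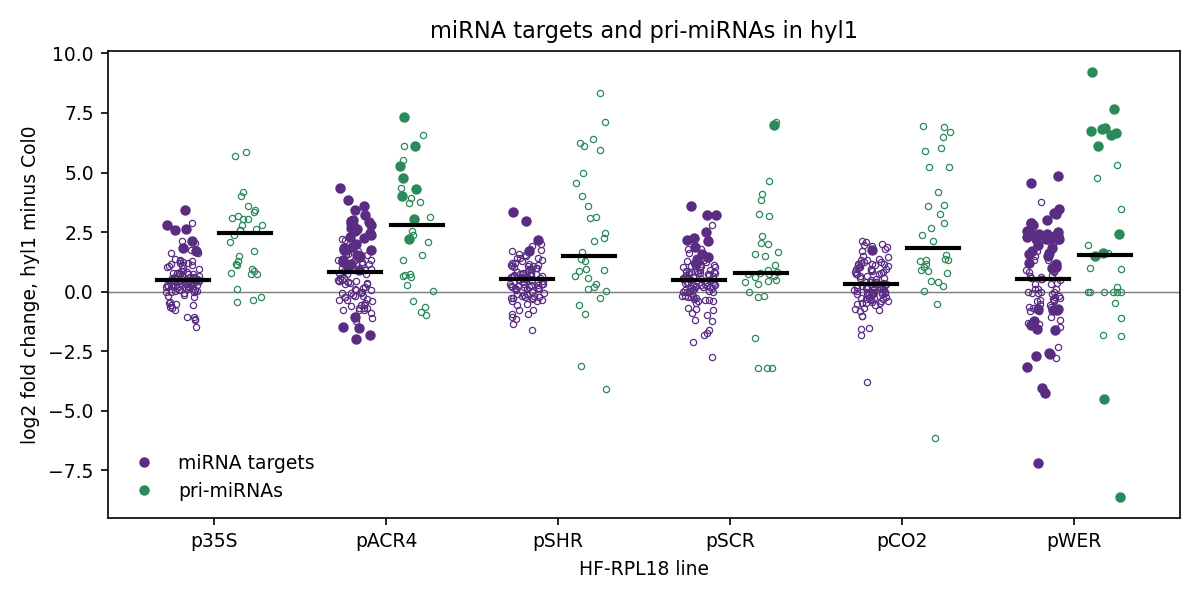
Fitted log2 fold change of 104 microRNA targets and 32 pri-miRNAs in each line, hyl1 minus Col0; filled points have an adjusted p under 0.05 and bars are medians. The median of the targets lies between 0.30 in the CO2 line and 0.82 in the ACR4 line, and fitted values of genes with 0 counts in a group have no defined size.

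Primary microRNA transcripts were near the detection limit in Col0 and higher in hyl1. Of 32 tested pri-miRNAs 12 rose, and adjusted over the list alone 14 rose (camera adjusted p = 4.09e-17, and 5.06e-04 with an estimated correlation). The median log2 fold change was 2.17 as fitted and 1.06 with the 21 genes that had a group at 0 counts set at their bound. MIR156c (AT4G31877) rose from 0 to 0.471 CPM in Col0 to 2.44 to 12.3 CPM in hyl1 libraries (edgeR adjusted p = 6.96e-07). MIR161 (AT1G48267), with 0 to 0.309 CPM in Col0 and 0 to 2.43 CPM in hyl1, passed at an adjusted p of 0.00105 but not without hyl1 WER replicate 1 (adjusted p = 1). TAS loci, the precursors of trans-acting small RNAs, did not move as a list (adjusted p = 0.68), with TAS1C (AT2G39675) alone called among 6, also adjusted over the list alone, at 0.61 (SE 0.17, adjusted p = 0.0161). In the small RNA machinery 5 of 19 genes rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell (adjusted p = 0.0641). HYL1, the mutated gene, is a member of this list and among the falls. AGO10 (AT5G43810) was at 0.68 (SE 0.13, adjusted p = 0.00108), but at an adjusted p of 0.984 without the WER libraries.

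Of the 5 lists of root layer markers, 3 passed the test in the mean of the lines. Endodermis markers, genes of the Casparian strip and suberin, had 11 of 19 higher and 1 lower in hyl1, or 15 and 1 adjusted over the list alone (median 0.84, adjusted p = 1.7e-08, and 0.121 with an estimated correlation). PER64 (AT5G42180), AT1G61590 and ESB1 (AT2G28670) rose by 1.49 (SE 0.23), 1.48 (SE 0.20) and 1.46 (SE 0.23), and CASP5 (AT5G15290) fell by 2.06 (SE 0.42). Stele markers had 13 of 24 higher and 2 lower, or 15 and 3 adjusted over the list alone (median 0.50, adjusted p = 1.58e-06, and 0.00647 with an estimated correlation), led by the sieve element genes SEOR1 (AT3G01680) at 2.03 (SE 0.20) and SEOa (AT3G01670) at 1.36 (SE 0.18). The direction of the stele list turned by line, with medians of 1.22 in ACR4, 1.65 in WER and 0.40 in SCR, where the list passed upward, 0.03 in 35S and −0.19 in SHR, where it did not pass, and −0.39 in CO2, where it passed downward (adjusted p = 9.67e-05). The share of the dominant transcripts was higher in hyl1 in the ACR4 and WER lines and lower in the SCR line. Epidermis and root hair markers had 9 of 21 lower, or 14 adjusted over the list alone (median −0.69, adjusted p = 7.57e-05, and 0.127 with an estimated correlation), among them the root hair regulator RSL4 (AT1G27740) at −1.25 (SE 0.26) and the iron transporter IRT1 (AT4G19690) at −0.97 (SE 0.19). By line the epidermis medians were −0.07 in 35S, −0.17 in WER, −0.34 in SHR, −0.45 in ACR4, −0.58 in CO2 and −1.25 in SCR. In the fit of only the 35S, SHR and CO2 lines SEOR1, SEOa and IRT1 did not pass (adjusted p = 0.826, 0.808 and 0.846). The columella and root cap list had 1 of 11 higher and 2 lower, or 3 and 3 adjusted over the list alone (adjusted p = 0.98), and the cortex list 2 of 8 higher and 2 lower in both counts (adjusted p = 0.94). The median of the cortex list was −0.06 and its mean −0.44, while its test pointed up. Nuclear genes of shoot photosynthesis had 3 of 10 higher, or 4 adjusted over the list alone (median 1.09, or 0.80 with bounds, adjusted p = 2.53e-04, and 0.00786 with an estimated correlation). RBCS1A (AT1G67090), a small subunit of Rubisco, rose by 2.195 (SE 0.17, adjusted p = 1.05e-07).

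Hormone and stress lists did not pass in the mean of the 6 lines. Among abscisic acid genes 4 of 8 fell, or 5 adjusted over the list alone (median −0.65, adjusted p = 0.0645), among them the cold-induced gene KIN2 (AT5G15970) at −1.35 (SE 0.18) and the phosphatase gene ABI1 (AT4G26080) at −0.53 (SE 0.10), which did not pass without the WER libraries (adjusted p = 0.112). Among auxin-induced genes 5 of 13 fell, also adjusted over the list alone (median −0.39, adjusted p = 0.582), with GH3.1 (AT2G14960) at −1.37 (SE 0.33) and IAA1 (AT4G14560) at −1.27 (SE 0.17). In single lines edgeR called auxin-induced genes only in ACR4 (3 of 13) and WER (10 of 13). For the abscisic acid and auxin lists fry, which asks only whether members move 1 way, gave an adjusted p of 0.00436 and 0.00635. Among jasmonate and touch genes 2 of 13 fell, also adjusted over the list alone (median −0.89, or −0.73 with bounds, adjusted p = 0.141), led by the calmodulin-like gene TCH3 (AT2G41100) at −1.05 (SE 0.27). The flavonoid list (8 genes, median −0.13, adjusted p = 0.582) had 0 genes called by edgeR, also adjusted over the list alone, 1 at an unadjusted p under 0.05 and 1 by DESeq2. The heat shock list (4 genes, adjusted p = 0.915) and the cell division list (5 genes, median 0.02, adjusted p = 0.915) had 0 genes called by edgeR, also adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2. The mean of each was below 0 (−0.07 and −0.00) while its test pointed up.

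In the 35S line, where the tagged ribosomes are not restricted to 1 layer, 21 genes were higher and 2 lower in hyl1, which is 91.3% higher, and a fit of the 4 libraries of this line alone called 500 genes, 53% of them higher. HSD4 and HSD7, with 0 counts in Col0 and 10.4 ± 0.406 CPM in hyl1 (SD, n = 2), were each at least 66.2-fold higher. AT1G52800 rose from 0.157 to 26.1 CPM (edgeR adjusted p = 3.35e-05), and AT3G59930 fell from 87.5 ± 8.66 to 6.65 ± 0.225 CPM (adjusted p = 0.00471). Of 104 microRNA targets 7 rose, and adjusted over the list alone 16 rose and 1 fell (median 0.47, adjusted p = 4.96e-23, and 1.2e-05 with an estimated correlation). The largest rises among them were MYB33 at 3.45 (SE 0.28), MYB65 at 2.80 (SE 0.43) and SULTR2;1 at 2.62 (SE 0.33). The shoot photosynthesis list was higher (median 0.80, adjusted p = 0.00435, and 0.0283 with an estimated correlation). Leaving out any 1 of the 4 libraries gave 10 to 12 called genes, with MYB33, AT1G52800, HSD4 and HSD7 among them each time. MYB65 lost its call in each of the 4 fits (adjusted p up to 0.523), AT3G59930 in 3 (up to 0.187) and SULTR2;1 without Col0 35S replicate 1 (0.0717).

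The ACR4 line had 1460 genes higher and 1955 lower in hyl1. Of 104 microRNA targets 32 rose and 5 fell, and adjusted over the list alone 35 rose and 7 fell (median 0.82, adjusted p = 4.84e-09, and 3.94e-04 with an estimated correlation). SULTR2;1 rose by 4.36 (SE 0.37), NF-YA2 by 3.59 (SE 0.48), MYB33 by 3.44 (SE 0.28) and ATHB-15 by 2.87 (SE 0.26). AT1G15540 rose from 0.0589 to 42.7 ± 1.55 CPM (adjusted p = 2.59e-06), while AT5G35940 fell by 5.67 on the log2 scale to 4.41 ± 0.147 CPM (adjusted p = 9.79e-04). CR4 (AT3G59420), the receptor kinase gene whose promoter drives this line, rose from 168 ± 21.2 to 1102 ± 87.6 CPM (adjusted p = 1.47e-05). Endodermis markers had 12 of 19 higher, or 13 adjusted over the list alone (adjusted p = 6.48e-08, and 0.138 with an estimated correlation), such as ESB1 at 2.87 (SE 0.60). Stele markers had 11 of 24 higher, or 13 with 1 lower adjusted over the list alone (adjusted p = 6.09e-08, and 0.00431 with an estimated correlation), such as BHLH32 (AT3G25710) at 2.42 (SE 0.33). Epidermis markers had 6 of 21 lower in both counts (adjusted p = 0.0287, and 0.424 with an estimated correlation). The columella and root cap list, the line's own layer, had 4 of 11 higher and 5 lower in both counts (median −1.27, adjusted p = 0.94), with CR4 among the higher and the root cap gene NAC070 (AT4G10350) at −3.78 (SE 0.93) among the lower. The share of the 10 dominant transcripts rose from 6.91% to 27.3% in the same libraries, and the mean mitochondrial share from 2.46% to 10.3%, with 15.01% in hyl1 ACR4 replicate 2. The count of 3415 was 7847 in a fit of the 4 ACR4 libraries alone and 5463 without hyl1 WER replicate 2 in the shared spread. Leaving out any 1 of the 4 libraries gave 1530 to 1817 called genes, and 19 of 47 named genes kept their calls each time, those with values in this paragraph among them except NAC070, which lost its call in 2 fits (adjusted p up to 0.111).

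In the SHR line, 18 genes were higher and 1 lower in hyl1. AT1G52800, with 0 counts in Col0, was at least 42-fold higher at 17.7 ± 2.68 CPM, and AT1G15540 at least 21.1-fold higher at 8.89 ± 1.71 CPM. MYB33 rose by 2.95 (SE 0.29, edgeR adjusted p = 2.24e-04) and MYB65 by 3.33 (SE 0.47, adjusted p = 0.00371). The only fall was in NSP3 (AT3G16390), a nitrile-specifier gene of glucosinolate breakdown, at −2.01 (adjusted p = 0.00371). Of 104 microRNA targets 4 rose, and adjusted over the list alone 19 rose (median 0.52, adjusted p = 7.65e-12, and 1.22e-04 with an estimated correlation). The shoot photosynthesis list was higher (median 2.29, or 0.91 with bounds, adjusted p = 1.03e-04, and 0.00593 with an estimated correlation) and the epidermis list lower (median −0.34, adjusted p = 0.0157, and 0.387 with an estimated correlation). The balance of 94.7% higher was 63 higher and 22 lower under DESeq2, 31 and 7 in a fit of the 4 SHR libraries alone, 48 and 24 without hyl1 WER replicate 2 in the shared spread, and 18 and 5 without a filter on low counts. The count was 3 without Col0 SHR replicate 1, 51 without Col0 SHR replicate 2, and 9 and 8 without hyl1 SHR replicates 1 and 2. AT1G52800 and MYB33 kept their calls in each. AT1G15540 and MYB65 lost theirs without Col0 SHR replicate 1 (adjusted p = 0.0697 and 0.147), and NSP3 in 2 fits (up to 0.145, without hyl1 SHR replicate 2).

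The SCR line had 123 genes higher and 317 lower in hyl1. Of 104 microRNA targets 12 rose, and adjusted over the list alone 18 rose and 2 fell (median 0.50, adjusted p = 5.57e-12, and 1.22e-04 with an estimated correlation). SULTR2;1 was at 3.595 (SE 0.36), MYB65 and MYB33 both at 3.22 (SE 0.45 and 0.28), and PHB (AT2G34710), a class III HD-ZIP gene, at 1.59 (SE 0.26). HSD4 and HSD7 rose from 0.0773 to 12.2 ± 1.1 CPM (edgeR adjusted p = 1.97e-04 and 1.9e-04). SEOR1 rose by 3.13 (SE 0.48) and the stele list with it (2 of 24 higher, or 5 adjusted over the list alone, adjusted p = 5.37e-04, and 0.0359 with an estimated correlation). Epidermis markers had 2 of 21 lower, or 10 adjusted over the list alone (median −1.25, adjusted p = 1.31e-10, and 0.0159 with an estimated correlation), PRP3 (AT3G62680) and COW1 (AT4G34580) at −1.80 (SE 0.42) and −1.60 (SE 0.37). In the same libraries the 10 dominant transcripts fell from 17.7% to 7.16% of the counts, and the 2 Col0 replicates stood apart in endodermis markers. The count of 440 was 983 without Col0 SCR replicate 1, 185 without Col0 SCR replicate 2, 135 without hyl1 SCR replicate 1 and 149 without hyl1 SCR replicate 2. A fit of the 4 SCR libraries alone called 1 gene, AT1G52820, higher by 5.21 (SE 0.27, adjusted p = 0.0247). PRP3 and COW1 lost their calls in 3 of these 4 fits each (adjusted p up to 0.734 and 0.568, without Col0 SCR replicate 2).

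In the CO2 line, 20 genes were higher and 14 lower in hyl1, a balance that turned under DESeq2 (55 higher, 74 lower) and without hyl1 WER replicate 2 in the shared spread (49 higher, 61 lower). CYP712A2, with 0 counts in Col0, was at least 68.9-fold higher at 20.6 ± 3.25 CPM, and AT1G15540 rose from 0.199 to 19.9 ± 6.8 CPM (edgeR adjusted p = 4.45e-04). Among the 14 falls were the xyloglucan transglucosylase gene XTH12 (AT5G57530) at −3.56 (SE 0.43, adjusted p = 5.64e-04) and the extensin genes AT5G06630 and EXT12 (AT4G13390) at −3.04 (SE 0.57, adjusted p = 0.0345) and −3.01 (SE 0.56, adjusted p = 0.0336). AGO2 alone rose among 104 microRNA targets, at 1.74 (SE 0.33, adjusted p = 0.0365), and 18 rose adjusted over the list alone (median 0.30, adjusted p = 1.1e-07, and 7.53e-04 with an estimated correlation). Stele markers were lower as a list (median −0.39, adjusted p = 9.67e-05, and 0.0202 with an estimated correlation) and endodermis markers higher (median 1.11, adjusted p = 3.22e-05, and 0.279 with an estimated correlation). Shoot photosynthesis genes were higher (median 1.09, adjusted p = 3.32e-05, and 0.00473 with an estimated correlation). Leaving out any 1 of the 4 libraries gave 9 to 16 called genes, with AT1G15540 and AT1G52800 among them each time. AGO2 and AT5G06630 lost their calls in each of the 4 fits (adjusted p up to 0.593 and 0.701), EXT12 in 3 (up to 0.69), CYP712A2 in 2 (up to 0.0883) and XTH12 without hyl1 CO2 replicate 2 (0.0531).

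The WER line had 3668 genes higher and 5401 lower in hyl1, with a median of −0.24 over all genes. SULTR2;1 rose by 4.86 (SE 0.38), the laccase gene LAC3 (AT2G30210) by 4.58 (SE 0.49), ATHB-15 by 3.27 (SE 0.27) and ARF4 (AT5G60450), an auxin response factor under TAS3 control, by 3.01 (SE 0.39), while LAC2 (AT2G29130) fell by 4.06 (SE 0.92). Of 104 microRNA targets 35 rose and 15 fell, and adjusted over the list alone 41 rose and 18 fell (median 0.55, adjusted p = 1.81e-05, and 0.00322 with an estimated correlation). AT1G15540, with 0 counts in Col0, was at least 73.3-fold higher at 10.4 ± 4.79 CPM, and HHP5 (AT4G38320), with 0 counts in hyl1, at least 150-fold lower from 23.8 ± 5.2 CPM. SEOR1 rose by 6.44 (SE 0.61) with 16 of 24 stele markers higher and 2 lower, or 18 and 2 adjusted over the list alone (adjusted p = 1.43e-07, and 0.00473 with an estimated correlation). AT1G61590 and PER64 rose by 4.53 (SE 0.54) and 4.09 (SE 0.65) with 13 of 19 endodermis markers higher and 1 lower in both counts (adjusted p = 1e-06, and 0.183 with an estimated correlation). TAS2 (AT2G39681) fell by 5.85 (SE 1.05), and the auxin-induced gene IAA1 by 3.36 (SE 0.42). Some of the genes named by the rule for this line lost their call in at least 1 fit with 1 library left out. The dominant transcripts held 1.83% of the counts in Col0 and 18.7% in hyl1, and mitochondrial genes 1.78% and 8.72%. The count of 9069 was 14378 without hyl1 WER replicate 1. In a fit of the 4 WER libraries alone it was 258, and the balance turned, with 203 higher and 55 lower.

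Single genes recurred across lines. AT1G15540, AT1G52800, AT1G52820, AT2G42247, CYP712A1, CYP76G1 (AT3G52970), HSD4 and HSD7 were called higher in all 6 lines, and MYB33, MYB65, TCP4, AGL16 and AT4G15390 in 5 of 6. In the 35S and SHR lines TCP4 (adjusted p up to 0.523 and 0.744) and AGL16 (up to 0.616 and 0.24) lost their calls in each of the 4 fits with 1 library left out, MYB65 in 4 and 1 of them, and HSD7 in 3 in the SHR line (up to 0.147). CYP712A1 (AT2G42250) went from 1.1 to 4.36 CPM in Col0 libraries to 20.5 to 82.1 CPM in hyl1 libraries. No library is shared between lines, but the spread estimated for each gene is. The lists of called genes are thus not independent, and the expected counts given here are only a guide. Of the genes called in the 35S and ACR4 lines 21 were higher in both, against 1.32 expected of independent lists of these sizes, and in the 35S and SHR lines 12, against 0.0163. The ACR4 and WER lines had 1205 genes higher in both (230.6 expected) and 1489 lower in both (455 expected), with an r of 0.61 across 16678 genes, which are not independent replicates. The SCR and WER lines had 109 genes higher in both, against 19.4 expected, and 36 lower in both, against 73.7.

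**Figure D3:**
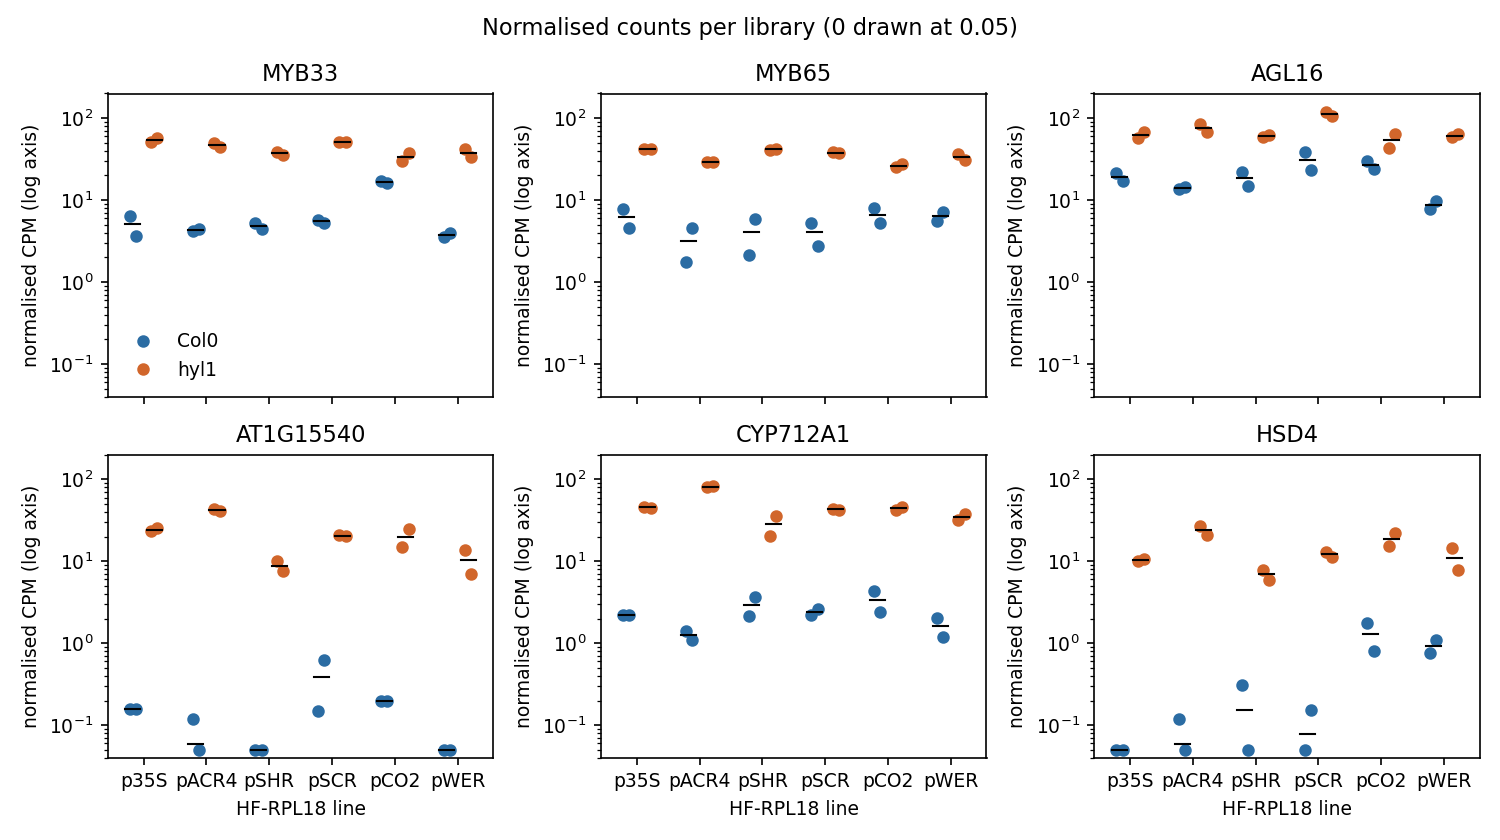
Normalised CPM of MYB33, MYB65, AGL16, AT1G15540, CYP712A1 and HSD4 in each of the 24 libraries, on a log axis, by line and genotype; dots are libraries, bars are means of 2, and values of 0 are drawn at 0.05. AT1G15540 lies at 0 to 0.619 CPM in Col0 and at 7.04 to 43.8 CPM in hyl1.

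The hyl1 effect differed between lines for 4122 genes (edgeR, 5 contrasts tested jointly), a count that was 10365 without hyl1 WER replicate 1 and 9 in a fit of only the 35S, SHR and CO2 lines. The smallest adjusted p were those of AT1G60095 (1.27e-07), one of the dominant transcripts, of IMS2 (AT5G23020), IMD1 (AT5G14200) and CYP83A1 (AT4G13770), genes of aliphatic glucosinolate synthesis (7.52e-07, 7.52e-07 and 3.84e-06), and of HHP5 (7.52e-07). Against the mean of the other 5 lines, 9 genes differed in the 35S line, 62 in the SHR line, 98 in the CO2 line, 557 in the SCR line, 1201 in the ACR4 line and 6613 in the WER line. The microRNA target list rose less in the CO2 line than in the other 5 (median difference −0.22, adjusted p = 0.000305, and 0.0696 with an estimated correlation), with MYB33 lower by −2.25 (SE 0.29, adjusted p = 0.00132).

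In Col0, the SCR line was marked by endodermis transcripts. CASP1 (AT2G36100), a membrane protein gene of the Casparian strip, was higher than in the 4 other layer lines by 4.89 (SE 0.30, edgeR adjusted p = 4.86e-09), the peroxidase gene PER64 by 4.82 (SE 0.38, adjusted p = 6.98e-08) and RWP1 (AT5G41040), a suberin acyltransferase gene, by 4.57 (SE 0.24, adjusted p = 1.42e-09). Of 19 endodermis markers 18 were higher, also adjusted over the list alone (median 3.85, adjusted p = 2.83e-31, and 0.00115 with an estimated correlation). SCR (AT3G54220) itself was higher by 2.21 (SE 0.26, adjusted p = 1.15e-05) at 58.2 ± 34.8 CPM. The most enriched genes with counts in every group were AT2G38390 at 5.40, AT5G09480 at 5.38 and AT4G11290 at 5.25. In all, 1200 genes were higher and 310 lower, 1510 together, and 566 without Col0 SCR replicate 1.

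The SHR line was marked by stele transcripts. The xylem protease genes XCP2 (AT1G20850) and XCP1 (AT4G35350) were higher by 3.63 (SE 0.17, edgeR adjusted p = 1.01e-09) and 3.48 (SE 0.18, adjusted p = 1.5e-09), and SHR (AT4G37650) itself by 3.599 (SE 0.58, adjusted p = 2.6e-04). Of 24 stele markers 18 were higher, also adjusted over the list alone (median 2.26, adjusted p = 4.86e-16, and 7.83e-05 with an estimated correlation). AT5G35116 was the most enriched gene, at 7.15 (SE 0.61), followed by AT1G27660 at 5.19 (SE 0.26). In all, 2230 genes were higher and 2210 lower, 4440 together, and 2244 and 2173 without Col0 SHR replicates 1 and 2. The line cannot be told apart from its batch in this comparison.

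The ACR4 line was marked by CR4 itself, higher by 4.92 (SE 0.20, edgeR adjusted p = 5.07e-11) at 168 ± 21.2 CPM, and by root cap genes. The NAC factor genes NAC070 (AT4G10350) and NAC015 (AT1G33280), which act in root cap maturation, were higher by 3.02 (SE 0.58, adjusted p = 0.0019) and 2.97 (SE 0.55, adjusted p = 0.0013), and the glucosidase gene BGLU35 (AT1G51470) by 4.28 (SE 0.53, adjusted p = 4.65e-05). In the hyl1 libraries the same contrast gave −0.35 for NAC070 and −0.02 for BGLU35. Most genes called and named by the rule for this line lost their call in at least 1 fit with 1 library left out. Of 11 columella and root cap markers 6 were higher and 2 lower, or 6 and 3 adjusted over the list alone (median 2.01, adjusted p = 0.0119, and 0.0754 with an estimated correlation). Stele markers had 9 of 24 lower, or 10 adjusted over the list alone (median −0.996, adjusted p = 5.48e-09, and 0.00726 with an estimated correlation), and endodermis markers 11 of 19 lower, or 15 (median −1.69, adjusted p = 7.78e-12, and 0.161 with an estimated correlation). In all, 1993 genes were higher and 873 lower, 2866 together, and 1035 and 916 without Col0 ACR4 replicates 1 and 2.

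The WER line was marked by epidermis genes, and some root cap genes were higher too. The homeodomain gene GL2 (AT1G79840) was higher by 2.24 (SE 0.26, edgeR adjusted p = 4.22e-06), IRT1 by 2.16 (SE 0.32, adjusted p = 5.31e-05) and PRP3 by 2.06 (SE 0.26, adjusted p = 1.28e-05). Of 21 epidermis markers 9 were higher, also adjusted over the list alone (median 0.69, adjusted p = 0.00243, and 0.129 with an estimated correlation). The columella and root cap list did not pass (adjusted p = 0.595), with 6 of 11 higher and 3 lower in both counts. Its median of 2.02 was still above that of the epidermis list, and near its median of 2.01 in the ACR4 line. Higher members included NAC070 at 3.18 (SE 0.58) and SMB (AT1G79580), another root cap NAC gene, at 2.24 (SE 0.45), and the lower members were the auxin efflux carrier genes PIN3 (AT1G70940) at −2.07 (SE 0.39) and PIN7 (AT1G23080) at −1.13 (SE 0.28), and NGR2 (AT1G72490) at −1.62 (SE 0.41). MYB66 (AT5G14750), the WER gene itself, was at 1.31 (SE 0.41, adjusted p = 0.0247) but lost its call without Col0 WER replicate 2 (adjusted p = 0.552) or Col0 SHR replicate 1 (0.0525). In all, 3464 genes were higher and 2744 lower, 6208 together, and 3687 without Col0 WER replicate 1. The balance turned under DESeq2 (3118 higher, 3754 lower) and among called genes with at least a 2-fold change (2118 higher, 2445 lower), and the line cannot be told apart from its batch.

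The CO2 line was not marked by its cortex list. AT1G62500, the CO2 gene, was at 2.00 (SE 0.96, edgeR adjusted p = 0.215) with 2.49 ± 0.127 CPM. Of 8 cortex markers 0 were called by edgeR, also adjusted over the list alone, 2 had an unadjusted p under 0.05 and 1 was called by DESeq2 (median 0.43, adjusted p = 0.161). Stele genes were higher in this line, with 5 of 24 called, or 9 adjusted over the list alone (median 0.52, adjusted p = 4.87e-04, and 0.0807 with an estimated correlation), among them SEOR1 at 2.27 (SE 0.35, adjusted p = 3.84e-04) and the phosphate exporter gene PHO1 (AT3G23430) at 1.69 (SE 0.21, adjusted p = 5.76e-05). In the hyl1 libraries this contrast gave −0.32 for SEOR1 and −0.06 for PHO1. Most genes called and named by the rule for this contrast lost their call in at least 1 fit with 1 library left out. The dominant transcripts held 26.9% of the counts in the Col0 CO2 libraries, against 1.83% to 17.7% in the other Col0 layer lines. In all, 1314 genes were higher and 1030 lower, 2344 together, and 541 and 1180 without Col0 CO2 replicates 1 and 2.

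**Figure D4:**
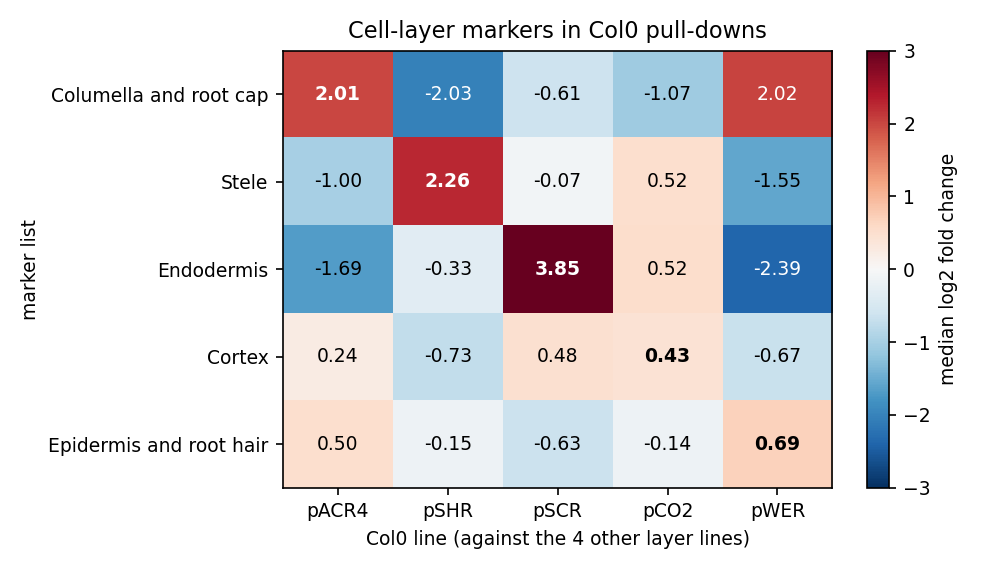
Median log2 fold change of 5 marker lists in each Col0 layer line against the 4 other layer lines, with the own layer of each line in bold. The own-layer medians are 2.01 in the ACR4 line, 2.26 in the SHR line, 3.85 in the SCR line, 0.43 in the CO2 line and 0.69 in the WER line.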

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

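The tests chosen only after the result was seen were those of hyl1 WER replicate 2 and of hyl1 RNA in the Col0 CO2 libraries, with the fits without the WER libraries and of only the 35S, SHR and CO2 lines.

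The hyl1 effect differed between lines for 4122 genes. The smallest adjusted p belonged to AT1G60095 (1.27e-07), to IMS2, HHP5 and IMD1 (7.52e-07 each) and to CYP83A1 (3.84e-06). The real assignment of genotypes called 4607 genes for the mean of the lines, and the highest of the other 59 splits of the libraries within lines called 3268. For the microRNA target list the smallest camera p of the other splits was 3.17e-08, against 6.45e-17 for the real one. In both tests 1 of 60 splits, the real one, gave a result as large, which is the smallest share that 60 splits can give. This argues against a random grouping of the libraries as the source of this count and of the list's rise in the mean. The splits do not address the share of the dominant transcripts, which differs by genotype in the ACR4, WER and SCR lines. No splits were run for the difference between lines.

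Gene lists whose hyl1 effect in 1 line differed from that in the other 5 lines were found by camera, with adjusted p given and the value with an estimated correlation after it. Endodermis markers were lower in the 35S line (median difference −1.03, adjusted p = 4.24e-10, then 0.207) and the SHR line (−1.11, 4.5e-07, then 0.354), and higher in the ACR4 line (1.01, 0.000515, then 0.650) and the WER line (1.51, 6.18e-05, then 0.530). Stele markers were lower in the 35S line (−0.46, 0.000946, then 0.0898), the SHR line (−0.62, 1.8e-06, then 0.0233) and the CO2 line (−1.13, 5.11e-16, then 0.000919), and higher in the ACR4 line (0.93, 2.02e-05, then 0.0363) and the WER line (1.63, 1.11e-06, then 0.0233). Epidermis markers were higher in the 35S line (0.40, 0.0355, then 0.650) and lower in the SCR line (−0.73, 0.0015, then 0.408). TAS loci were higher in the ACR4 line (1.63, 0.00549, then 0.0728), and flavonoid genes were lower in the CO2 line (−0.86, 0.0353, then 0.667). The microRNA targets rose less in the CO2 line (−0.22, 0.000305, then 0.0696).

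The ACR4, WER and SCR lines, with 3415, 9069 and 440 called genes, were those in which the share of the dominant transcripts differed most between genotypes. Across 16680 genes, which are not independent replicates, the hyl1 effect correlated with the difference of the SHR and CO2 lines from the 35S line at r of 0.307 in the ACR4 line and 0.359 in the WER line, where hyl1 had the higher share, and at −0.516 in the SCR line, where Col0 had it. A different share of these transcripts may therefore account for part of the calls in the 3 lines. Whether hyl1 replicate 2 is the whole source of the count in the WER line could not be decided. At 1 spread that leaves replicate 2 out, 9335 genes were called from replicate 1 alone, against 13276 from the mean of both. Of the 9335 genes, 7562 were shared with the mean in the same direction. That spread leaves out the disagreement of the 2 hyl1 WER libraries, so many calls from 1 library do not separate the causes. Replicate 1 correlated less with replicate 2 (r of 0.752) than with the Col0 WER libraries (0.786 and 0.794). Its r was higher with some libraries of other layer lines, such as Col0 CO2 replicate 2 (0.842), and lower with the 35S libraries (0.752 to 0.782). A fit of the 4 WER libraries alone, which keeps the disagreement of the hyl1 replicates in its spread, called 258 genes. In the ACR4 line, the hyl1 libraries correlated with the Col0 ACR4 libraries at r of 0.883 to 0.893. With Col0 SCR replicate 2, hyl1 ACR4 replicates 1 and 2 correlated at 0.938 and 0.936. A line-specific effect of hyl1 stays open, since genotype and share move together in these lines.

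The smaller rise of microRNA targets in the CO2 line was weighed as the second pattern, with MYB33 differing from the other lines by −2.25 (SE 0.29, edgeR adjusted p = 0.00132). In CPM of the unscaled library totals, MYB33 was at 15.3 ± 0.775 in the Col0 CO2 libraries and 5.01 ± 1.57 in the other Col0 libraries (SD). In hyl1 it was at 30.7 ± 5.35 in the CO2 libraries and 47.3 ± 17.7 in the others. Its smaller rise thus came with a higher level in Col0, but 1 gene does not settle the list. Mixing of hyl1 RNA into the Col0 CO2 libraries is argued against by AT1G15540, at 0.184 CPM of the unscaled library totals there where 5.41 CPM would be needed to reach the MYB33 level, and by AT1G52800, at 0.277 against 5.94 CPM in the same unit. Stele markers summed to 664 CPM in the Col0 and 487 CPM in the hyl1 CO2 libraries (list median −0.39, adjusted p = 9.67e-05, and 0.0202 with an estimated correlation), but this difference as the source of the smaller rise is argued against by an r of 0.0165 across the 104 targets between the CO2 minus 35S effect and the enrichment in the Col0 SHR line. A non-specific RNA share in both genotypes could lower the response and stays open, with a list median in CO2 against the 4 other layer lines of 0.17 in Col0 (camera p = 0.0161, and 0.0619 with an estimated correlation) and of −0.09 in hyl1 (camera p = 0.0617). A lower dependence of cortex microRNAs on HYL1, and the HYL1 reads left in the hyl1 CO2 libraries (5.34 against 10.9 CPM in Col0), were not tested as sources and stay open too. The hyl1 SHR libraries kept more HYL1 reads (9.21 against 14.03 CPM in Col0). The median of the target list was 0.52 in that line and 0.30 in the CO2 line, so more HYL1 reads did not go with a smaller rise there.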

How the results depend on the processing

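The fits without the WER libraries, of only the 35S, SHR and CO2 lines, and with hyl1 WER replicate 2 left out of the shared spread were chosen after the results were seen.

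The microRNA target list kept its direction and its call in all 7 hyl1 comparisons under each alternative run on it. With 1 library left out in turn the list still passed in each fit, and its weakest result was in the WER line. Of the values for single named genes under an alternative, 4920 kept direction and call, 655 lost the call, 4, all of HYL1 in the 35S, ACR4 and SCR lines, gained one and 15 changed sign or, in 1 case, came to 0. Of the counts of called genes, 151 stayed within 1.5 times and 63 did not. The cause was not tested for any of the changes below, except that fits of fewer libraries have fewer degrees of freedom. Depth sets the lower bounds given for genes with 0 counts in a group, and totals were lowest in the SHR line (2868803 to 4018367 counts).

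For the mean of the lines, 4607 genes became 775 (401 higher, 374 lower) with only the 35S, SHR and CO2 lines, 2738 without the WER libraries, and 3687 to 9487 with 1 library left out. Genes whose effect differs between lines, 4122, became 9 with only the 35S, SHR and CO2 lines and 3079 to 10365 with 1 library left out. With 1 library left out the 35S line gave 10 to 12 genes (23 with all), ACR4 1530 to 1817 (3415), SHR 3 to 51 (19), SCR 135 to 983 (440), CO2 9 to 16 (34) and WER 7208 to 14378 (9069). A lone library left in a group was assumed to vary like the other groups.

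A fit of the 4 libraries of a line gave 500 genes in the 35S line (53% higher, against 91.3%), 7847 in ACR4, 38 in SHR (31 higher, 7 lower, against 18 and 1), 1 in SCR (AT1G52820, higher, against 123 higher and 317 lower), 90 in CO2 and 258 in WER (203 higher, 55 lower, against 3668 and 5401). DESeq2 gave 67 in the 35S line, 85 in SHR (63 higher, 22 lower), 774 in SCR and 129 in CO2 (55 higher, 74 lower). Without hyl1 WER replicate 2 in the shared spread there were 54 in the 35S line, 5463 in ACR4, 72 in SHR (48 higher, 24 lower), 810 in SCR and 110 in CO2 (49 higher, 61 lower). Library sizes without organelle genes and RPL18B gave 271 in SCR. Without a filter on low counts the SHR line had 18 higher and 5 lower.

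Same-numbered replicates did not deviate together, with correlations from −0.0878 in the 35S line to 0.0698 in the SCR line, so the numbers share no pairing. With the replicate number as a block the counts were 9 in the 35S line, 7 in SHR, 267 in SCR, 11 in CO2 (8 higher, 3 lower) and 2168 for the difference between lines, and the other counts moved by less than 1.5 times, with 3558 for the mean.

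For the Col0 layers, leaving out hyl1 WER replicate 2 from the shared spread gave 4857 genes in ACR4 (2866 in full), 6756 in SHR (4440), 2722 in SCR (1510) and 4367 in CO2 (2344). The same contrast in the hyl1 libraries gave 723 in ACR4, 2555 in SHR (1659 higher, 896 lower), 4991 in SCR (3024 and 1967), 1346 in CO2 (1002 and 344) and 8545 in WER (3897 and 4648), and the columella list lost its call in ACR4 (adjusted p = 0.207). With 1 library left out the counts were 916 to 2920 in ACR4, 2173 to 4567 in SHR, 566 to 1868 in SCR, 541 to 2581 in CO2 and 3687 to 6087 in WER. In these fits most of the called genes named for SHR, SCR and WER kept their calls each time. Most of those named for ACR4 and CO2 lost theirs at least once. RLE size factors split the CO2 layer into 1487 higher and 711 lower and no filter into 1236 and 632, against 1314 and 1030. DESeq2 split ACR4 into 2059 and 1606, SCR into 1379 and 626, and WER into 3118 and 3754, where the median of all genes was −0.104 (0.00555 with the planned settings).

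Signs changed in these cases, with 1 exception named. BHLH32 was at −0.04 with only the 35S, SHR and CO2 lines. In the WER line CASP2 was at −6.21 without hyl1 WER replicate 1. MIR169b in that line changed no sign but came to 0 without hyl1 WER replicate 2, and ran from 0 to 8.64 with 1 library left out. In the hyl1 libraries BGLU35 was at −0.02 and NAC070 at −0.35 in ACR4, JKD at −0.85 in SHR and SEOR1 at 0.90 in WER. In the CO2 layer they gave −0.97 for MGP, −0.69 for PIN7, −0.02 for AT1G62500, −0.52 for SEOa, −0.32 for SEOR1, −0.06 for PHO1, −1.18 for AT4G29200 and −0.22 for NUC.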

Other observations

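The neighbour count and the correlation with motif position were chosen after the values were seen.

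Several of the strongest rises in hyl1 lay close to each other in the genome. Of 23 genes with a fitted rise over 8-fold in the mean of the lines, 7 had another such gene within 2 tested genes. In 2000 random draws the mean was 0.11 and the highest value 4 (permutation p = 0.0005, the smallest these draws can give). The 7 genes were AT1G52790, AT1G52800 and AT1G52820, AT2G42247 with CYP712A1, and CYP93D1 with CYP712A2. Without stated use of strand, reads from overlapping neighbours cannot be told apart.

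The last pattern weighed was the small set of transcripts that dominate the layer pull-downs and not the 35S pull-downs. Of the 10 most over-represented, 8 encode the residues DYKxxD, the start of the FLAG epitope, such as DYKELD in AT5G35200 and DYKDID in AT1G64880, against 22 of 7551 other genes (0.291%, one-sided Fisher's exact p = 9.93e-19). A candidate explanation is that the anti-FLAG resin binds nascent proteins with this motif, and the 30 genes with DYKxxD had a median log2 difference of 2.12 between layer and 35S lines, against −0.50 to −0.29 for 5 other orders of the 3 first residues. Long coding sequences are argued against by the median of −0.46 in 150 length-matched genes without the motif. Whether the motif must have left the ribosome could not be decided, with 0 genes holding it in the last 40 residues, and a correlation of the difference with the residues after the motif (Spearman rho 0.636 across the 30 genes, permutation p = 0.0003) is not separated from protein length, which correlated with the difference at a rho of 0.519 across all genes searched.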
